A study of Homo sapiens with 18 samples.

How the data were processed

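RNA of the cytosolic fraction of PC-3 cells was sequenced from 18 libraries: sheared and static cells at 3 h, 12 h and 24 h, with 3 replicates each. Per the labels and processing notes, the authors aligned reads with STAR to GRCh38.p13 and tested with DESeq2; versions, the read counter, its annotation and its strand setting are not given in the sources used here. The deposited count table holds the authors' raw read counts per NCBI Gene ID, with no normalization. The authors' 3 tables, 1 per time, hold log2 fold changes of sheared over static cells. Per the file headers they also hold the p-value of each gene and its adjusted p-value, the column used here. Reads were not analysed here.

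The count table covered 28395 Gene IDs. Symbols came from the RefSeq annotation of GRCh38.p14 for 27745 of them, used for names only, and 650 had none. Length, GC content and positions came from GENCODE 29 for 25457 of them. None of the Gene IDs was a gene encoded in the mitochondrial genome, so the list of the mitochondrially encoded respiratory chain had 0 members and was not tested. Depth ranged from 16400487 to 25862360 counts per library, and the uncertainty of low counts covers counting error and the spread between pools. Replicates of a group differed by more than counting error, with a chi-square per degree of freedom of 4.44 to 143, and no pair of libraries was identical.

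Samples were grouped by treatment and time as the labels give them. At 3 h the columns of the count table were matched to samples by the time and letter of the library names in the labels, with the letter for the treatment read as in the 12 h and 24 h names. Per the labels, the sheared and static libraries of 1 replicate number within a time came from 1 pool of cells, so pool was fitted as a block. As a check of that pairing, the correlation across genes of deviations from the group mean (log2 CPM), between a sheared and a static library of the same replicate number, was 0.0881 to 0.299 at 3 h, -0.148 to 0.245 at 12 h and 0.379 to 0.504 at 24 h. That of other sheared and static libraries was -0.242 to 0.130, -0.385 to 0.233 and -0.296 to -0.0924. The pools of different times are independent.

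Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15189 genes. The test was edgeR 4.0.16 in R 4.3.3, with TMM factors and the legacy quasi-likelihood F test with robust dispersion. A single model of all 18 libraries had 9 pools as blocks and a shear effect per time, with 6 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method at 0.05. Differences between times, and the mean over times, were contrasts of the same model. Static 24 h and 12 h cells were compared in a model of the 9 static libraries over 14804 genes. Standard errors are the size of the log2 fold change over the square root of F. CPM values of named genes use TMM factors; those of MALAT1 given by time and treatment, of 1 library, and of summed lists use total counts. A prior count of 2 was used for log2 CPM. The smallest p that an exact permutation of 3 against 3 can give is 0.1, so no per-gene permutation test was made.

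Genes are named by a rule fixed before the data were examined. It takes, at each time, the 12 largest rises and the 12 largest falls among genes with an adjusted p below 0.05, the same direction in all 3 pairs, a mean log2 CPM of at least 1 and a symbol. It also takes the 5 smallest p-values of each difference between times, 8 rises and 8 falls in static cells with all 24 h libraries apart from all 12 h ones, and up to 4 members of each described list by p. A further 12 genes are always named, among them ATF3, EGR1, FOS, CCN1, CCN2, HK2, LDHA, SLC2A1, HMGCS1, CDH1 and VIM. Of the genes that the rule took, the text gives those that best describe a group, and a few are not reported here.

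The gene lists were also written before the data were examined: 35 lists, of which 34 had at least 5 tested members. They were tested with camera of limma 3.58.1 at its preset correlation, adjusted over 102 tests of list and time, then with an estimated correlation and with fry. In static cells only the members past the threshold were counted. Lists of androgen-dependent prostate cells, haematopoietic cells, and fibroblast and endothelial cells stand for other cell types, and nuclear-retained RNAs for the purity of the cytosol.

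The fits were tested on simulated counts, drawn with the fitted levels of each pool and the gene-wise dispersions of the real data, no shear effect and 200 changed genes. At 1.5-, 2- and 4-fold, 34.3%, 71.6% and 90.9% of changed genes were recovered at 3 h with 6 false among 137 calls. At 12 h the shares were 35.8%, 70.1% and 92.4% with 7 false among 139, and at 24 h 38.8%, 71.6% and 93.9% with 10 false among 146. For static cells they were 43.3%, 83.6% and 92.4% with 9 false among 155. The simulated list was recovered with 0 other calls among 102. Genes were drawn independently there, so the simulation cannot show the error rate of the list test when members are correlated. In the real data the estimated correlation at 24 h was 0.577 for the G2/M and mitosis list. Each simulated gene also had the same dispersion at all times. The chi-square per degree of freedom of the real replicates went from 4.44 (static 3 h, 1 and 2) to 143 (sheared 24 h, 2 and 3). The simulation therefore cannot show how recovery and false calls differ between times.

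Alternatives fixed before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, at least 1 CPM in 3 libraries, no replicate block, the 6 libraries of a time alone, the test without robust dispersion, and leaving out each pair or each static library. Alternatives added after seeing the data were GC and length offsets, the non-legacy quasi-likelihood test, and leaving out the 24 h replicate 3 pair in the results of 3 h and 12 h and of the lists. Figures and tables were made with Python 3.11.15.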

Results

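PC-3 cells, a human prostate cancer line, were given brief fluid shear stress by passage through a syringe and needle, or were kept as a static suspension. Both were then held in suspension in wells coated to prevent attachment, for 3 h, 12 h or 24 h. RNA of the cytosolic fraction, obtained by detergent lysis, was sequenced from 18 libraries in 6 groups of 3. Within a time, the sheared and the static library of 1 replicate number came from 1 pool of cells, so the shear comparison was paired. The series asks how a short exposure to shear changes the cells, with metabolism and metastatic behaviour as its themes. Libraries held between 16400487 and 25862360 counts, and this depth sets the precision of every value for genes of low abundance. Tests covered 15189 genes, or 14804 in the comparison of static cells.

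Libraries separated first by time in suspension. The first principal component held 47.1% of the variance and placed the 3 h libraries between -69.2 and -60.9, the 12 h libraries between 5.86 and 22.7, and the 24 h libraries between 32.2 and 63.3. The 3 h libraries also carried another batch date than those of 12 h and 24 h, so between 3 h and the later times the time and the batch date cannot be told apart. The sheared 24 h replicate 3 library stood apart. Its TMM factor was 0.721, 17007 genes were detected in it, and its 100 most abundant genes took 28.2% of its counts. MALAT1, an RNA retained in the nucleus, had 49.3 CPM in that library.

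At 3 h, sheared cells held more transcript of immediate early genes, which are induced within minutes to hours of a stimulus. Many of them, but not all, encode transcription factors. NR4A3, an orphan nuclear receptor, rose from 1.74 ± 0.441 to 29 ± 0.273 CPM (mean ± SD, n = 3 per group), a log2 fold change of 4.07 ± 0.23 (SE, adjusted p = 1.85e-08, edgeR). Its relative NR4A2 rose from 11.1 ± 0.363 to 108 ± 26.9 CPM, by 3.25 ± 0.25 (adjusted p = 8.09e-06). The cytokine gene IL11 rose from 4.46 ± 1.26 to 55.6 ± 24.0 CPM, by 3.57 ± 0.24 (adjusted p = 2.67e-07). CD55, which protects the cell surface against complement, rose from 121 ± 15.6 to 415 ± 19.8 CPM, by 1.78 ± 0.16. Further rises were those of the small GTPase genes RRAD (2.97 ± 0.28), RASD1 (2.41 ± 0.19) and GEM (1.74 ± 0.20), and of the secreted metalloprotease gene ADAMTS1 (2.12 ± 0.19).

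Of the 30 immediate early genes tested at 3 h, 11 rose and none fell past the threshold over all genes; adjusted over the list alone, 22 rose and 1 fell. Their median log2 fold change was 1.00 (camera adjusted p = 4.27e-48, and adjusted p = 0.0916 with an estimated correlation). The number that rose was 5, 7 or 6 without 3 h replicate 1, 2 or 3, and 19 or 20 without 24 h replicate 2 or 3. KLF4, a zinc finger transcription factor, rose by 1.55 ± 0.12 (adjusted p = 9.53e-07), and the AP-1 subunit JUND by 1.12 ± 0.12. ATF3, a stress-induced transcription factor, rose from 51.7 ± 5.02 to 226 ± 30.1 CPM, by 2.12 ± 0.31 (adjusted p = 0.00894), but its adjusted p was 0.0869 without replicate 1 and 0.0605 without replicate 3 of that time. FOS (1.62, adjusted p = 0.0344) and EGR1 (1.33, adjusted p = 0.0312) lost their calls without any 1 of the pairs: without 3 h replicate 1, 2 or 3 the adjusted p of FOS was 0.0936, 0.148 or 0.288, and that of EGR1 0.121, 0.171 or 0.521. MYC, which drives growth and ribosome production, rose from 158 ± 18.7 to 365 ± 49.3 CPM, by 1.21 ± 0.14 (adjusted p = 8.63e-05). In the same 3 h libraries MALAT1, a sign of how cleanly the cytosol was separated, was at 28.7 ± 2.71 CPM in static and 15.6 ± 0.627 CPM in sheared libraries (-0.82, adjusted p = 0.778). The 2 groups did not overlap, with 26.6 to 31.7 CPM in static and 14.9 to 16.1 CPM in sheared libraries. The test takes its spread from the libraries of all times, so its p does not rule out a difference in purity at 3 h.

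Among the falls at 3 h were transcripts of cell division. CCNF, a cyclin that acts in a ubiquitin ligase, fell from 29.8 ± 1.82 to 14.9 ± 1.62 CPM (-1.0 ± 0.15, adjusted p = 6.98e-04). Of the 37 genes of the G2/M and mitosis list, none rose and 10 fell; adjusted over the list alone, 24 fell. Without 3 h replicate 1, 2 or 3, 2 of them fell and the median was -0.43, -0.43 or -0.42, and without the replicate block 0 fell with a median of -0.40. Of the pairs of other times, 6 fell without 12 h replicate 2 or 24 h replicate 1, and 22 without 24 h replicate 3. The median was -0.40 (camera adjusted p = 5.28e-25, and adjusted p = 0.310 with an estimated correlation). The kinesin gene KIF14 changed by -0.89 ± 0.12 and the kinetochore gene CENPF by -0.85 ± 0.12, and both lost their calls without the replicate block (adjusted p = 0.619 and 0.203). PTX3, a secreted pattern recognition protein, fell as well (-1.0 ± 0.13), as did ARHGAP24, a GTPase-activating protein (-0.99 ± 0.15).

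Other lists that passed at 3 h had smaller medians. YAP/TAZ target genes, which respond to mechanical cues, had 3 of 23 members that rose and a median of 0.16 (5 rose adjusted over the list alone; camera adjusted p = 8.54e-04, and adjusted p = 0.606 with an estimated correlation). NF-kB targets and inflammatory cytokines had 2 of 28 members that rose and 1 that fell, with a median of 0.13 (4 and 1 adjusted over the list alone; camera adjusted p = 4.50e-04, and adjusted p = 0.712 with an estimated correlation). Cytosolic ribosomal proteins had 0 of 48 members past the threshold, a median of 0.13 and a camera adjusted p of 1.11e-04 (adjusted p = 0.833 with an estimated correlation). MYC targets and ribosome biogenesis genes had 2 of 31 that rose and a median of 0.13 (camera adjusted p = 0.00244, and adjusted p = 0.751 with an estimated correlation). Epithelial genes had 0 of 30 past the threshold and 4 that rose adjusted over the list alone (camera adjusted p = 0.00857, and adjusted p = 0.606 with an estimated correlation). The hypoxia list and the nuclear-encoded respiratory chain list had medians of 0.14 and 0.10, with 0 members past the threshold in either (camera adjusted p = 0.0180 and 0.0103, and adjusted p = 0.833 for both with an estimated correlation). Without 3 h replicate 3, 1 YAP/TAZ target gene rose, and without any 1 of the 3 h pairs 1 gene of the MYC list rose and 0 of the NF-kB list fell. Of the NF-kB list 2 fell without 12 h replicate 3 or 24 h replicate 2, and 5 rose and 2 fell without 24 h replicate 3, where 3 epithelial genes rose.

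Counted over all genes, 170 were higher and 52 lower in sheared cells at 3 h, 71 and 9 of them by at least 2-fold, and all 222 moved the same way in the 3 pairs. These counts depended on the pairs and the fit. Genes higher in sheared cells at 3 h numbered 71, 70 or 76 without replicate 1, 2 or 3 of that time, 304 without 24 h replicate 3, 58 with no replicate block, 331 with no filter on low counts and 816 in a fit of the 6 libraries of the time alone. Genes lower in sheared cells at 3 h numbered 9, 10, 13, 142, 6, 119 and 650 under the same settings in that order, and 79 with DESeq2.

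**Figure D1:**
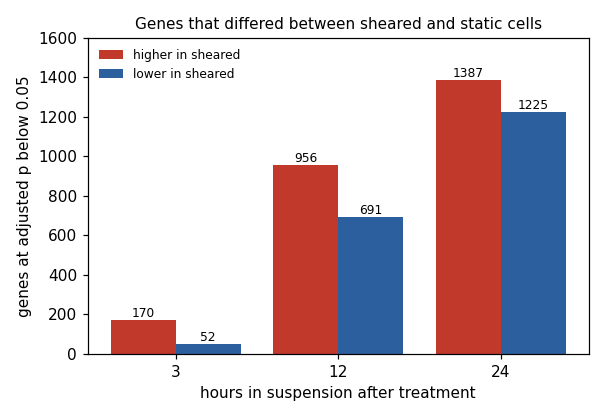
Number of genes higher (red bars) and lower (blue bars) in sheared than in static cells at 3 h, 12 h and 24 h, at an adjusted p below 0.05 (edgeR, 3 pairs per time). The counts were 170 and 52 at 3 h, 956 and 691 at 12 h, and 1387 and 1225 at 24 h. In fits of the 6 libraries of a time alone, both counts were larger at 3 h than at 24 h. The counts therefore do not rank the times by the size of the response.

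At 12 h the largest changes included genes of a channel, a receptor, transporters and protein-modifying enzymes. AQP3, a channel for water and glycerol, rose from 7.55 ± 0.701 to 30.5 ± 8.49 CPM, by 1.99 ± 0.19 (adjusted p = 1.11e-05, edgeR). The sialyltransferase gene ST6GAL2 rose from 8.01 ± 0.429 to 26.6 ± 3.53 CPM, by 1.72 ± 0.14, and the oxytocin receptor gene OXTR from 5.92 ± 0.299 to 17.2 ± 3.78 CPM, by 1.52 ± 0.20. PADI3, an enzyme that converts arginine in proteins to citrulline, fell from 6.64 ± 0.677 to 0.802 ± 0.403 CPM (-3.08 ± 0.32, adjusted p = 1.53e-05), and its relative PADI2 from 53.6 ± 6.58 to 15.2 ± 1.81 CPM (-1.82 ± 0.17). TCN1, a vitamin B12 binding protein, fell from 142 ± 24.4 to 28.4 ± 7.97 CPM (-2.35 ± 0.19). The amino acid transporter genes SLC7A8 (-2.44 ± 0.27) and SLC7A11 (-1.57 ± 0.16) fell as well.

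Transcripts of lipid synthesis were lower at 12 h. Of 25 genes of cholesterol synthesis and uptake, none rose and 15 fell, with a median of -0.54 (20 fell adjusted over the list alone; camera adjusted p = 1.70e-14, and adjusted p = 0.239 with an estimated correlation). SQLE, which makes squalene epoxide on the way to cholesterol, fell from 229 ± 10.8 to 127 ± 17.5 CPM (-0.85 ± 0.12, adjusted p = 3.57e-04). Of 17 genes of fatty acid synthesis, none rose and 9 fell, with a median of -0.67 (11 fell adjusted over the list alone; camera adjusted p = 1.33e-11, and adjusted p = 0.155 with an estimated correlation). Among them were the desaturase genes FADS2 (-1.05 ± 0.12) and FADS1 (-0.84 ± 0.12) and ACSS2, which makes acetyl-CoA from acetate (-0.98 ± 0.13). HMGCS1, an early enzyme of cholesterol synthesis, passed (-0.75, adjusted p = 0.0169), with an adjusted p of 0.0666, 0.162 or 0.0758 without 12 h replicate 1, 2 or 3. The falls in the cholesterol list numbered 10, 8 or 4 without these pairs in that order.

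Interferon-stimulated genes, which restrict viruses, were lower at 12 h. Of 35 tested, none rose and 21 fell, with a median of -0.60 (1 rose and 26 fell adjusted over the list alone; camera adjusted p = 4.85e-19, and adjusted p = 0.155 with an estimated correlation). OAS2, which senses double-stranded RNA, fell from 36.6 ± 5.6 to 14.5 ± 2.49 CPM (-1.34 ± 0.15, adjusted p = 3.18e-05), and MX2 from 5.63 ± 0.838 to 2.12 ± 0.336 CPM (-1.41 ± 0.22). Targets of the oxidative stress regulator NRF2 had 3 of 25 members that rose and 4 that fell, with a median of -0.15 (3 and 6 adjusted over the list alone; camera adjusted p = 0.0359, and adjusted p = 0.319 with an estimated correlation). FTH1, the ferritin heavy chain, rose by 0.64 ± 0.11, and AKR1B10, an aldo-keto reductase, fell (-1.54 ± 0.20). The unfolded protein response list had 5 of 22 members that fell, with a median of -0.17 (5 adjusted over the list alone; camera adjusted p = 0.0161, and adjusted p = 0.833 with an estimated correlation). Without 12 h replicate 1, 2 or 3, the falls numbered 16, 7 or 16 in the interferon list, where 1 gene rose without replicate 3, and 3, 1 or 3 in the unfolded protein response list, and the rises among NRF2 targets 1, 1 or 2. In the unfolded protein response list 1 gene rose without 24 h replicate 1 or 3.

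Ribosomal protein transcripts rose at 12 h. Of 48 cytosolic ribosomal proteins, 47 rose, with a median of 0.56 (48 adjusted over the list alone; camera adjusted p = 1.74e-34, and adjusted p = 0.319 with an estimated correlation). RPSA rose by 0.61 ± 0.11 and RPS12 by 0.73 ± 0.13. Ribosomal protein transcripts made up 5.47% ± 0.323 of counts in static and 7.23% ± 0.341 in sheared libraries (SD, n = 3), and the 100 most abundant genes 18.8% ± 0.605 and 22.6% ± 1.40. MYC targets and ribosome biogenesis genes had 7 of 31 that rose and a median of 0.29 (9 adjusted over the list alone; camera adjusted p = 6.39e-05, and adjusted p = 0.606 with an estimated correlation). Without 12 h replicate 1, 2 or 3, the rises numbered 23, 9 or 48 among ribosomal proteins and 2, 1 or 4 in the MYC list, where 1 gene fell without replicate 3.

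Some genes of the respiratory chain, the cytoskeleton and the cell cycle also rose at 12 h. No random lists matched on abundance and length were drawn for these lists, so a trend shared with other genes stays open for them. In the nuclear-encoded respiratory chain 8 of 49 rose and the median was 0.27 (19 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.34e-07, and adjusted p = 0.547 with an estimated correlation). Of 24 glycolysis genes 0 rose and 1 fell (camera adjusted p = 0.273, and adjusted p = 0.926 with an estimated correlation), and of 25 TCA cycle genes 1 rose and 1 fell (camera adjusted p = 0.545, and adjusted p = 0.941 with an estimated correlation). Of 23 YAP/TAZ target genes 7 rose, with a median of 0.37 (9 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.61e-05, and adjusted p = 0.452 with an estimated correlation). SRF and actin cytoskeleton genes had 2 of 25 that rose, the cofactor FHL2 (0.75 ± 0.11) and the cytoplasmic actin ACTG1 (0.79 ± 0.12), with 9 adjusted over the list alone (camera adjusted p = 0.00464, and adjusted p = 0.833 with an estimated correlation). The membrane repair and ESCRT list had 5 of 29 that rose, CAV1 of caveolae among them (0.98 ± 0.10), with 8 adjusted over the list alone (camera adjusted p = 0.0173, and adjusted p = 0.239 with an estimated correlation). Of 32 G1/S and DNA replication genes 6 rose, with a median of 0.31 (8 adjusted over the list alone; camera adjusted p = 4.28e-05, and adjusted p = 0.790 with an estimated correlation). Of 37 G2/M and mitosis genes 11 rose, with a median of 0.27 (13 adjusted over the list alone; camera adjusted p = 8.10e-07, and adjusted p = 0.751 with an estimated correlation). Without 12 h replicate 1, 2 or 3, the rises numbered 2, 0 or 12 in the respiratory chain, 0, 0 or 3 in glycolysis and 0 each time in the TCA cycle. They numbered 4, 5 or 5 among YAP/TAZ targets, 2, 2 or 7 in the SRF list, 3, 2 or 3 in membrane repair, 2, 1 or 3 in G1/S and 3, 1 or 8 in G2/M, and the glycolysis fall was lost without replicate 2. Without 24 h replicate 3 they numbered 17 in the respiratory chain (where 1 fell), 11 in the SRF list, 8 in membrane repair, 17 in G2/M and 4 in glycolysis. Without any 1 of the 3 h pairs 2 rose in membrane repair and 7 in G2/M, and membrane repair had 3 without 24 h replicate 1 and 8 without 24 h replicate 2, where the SRF list had 4 and glycolysis 1.

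In total 956 genes were higher and 691 lower in sheared cells at 12 h, 101 and 154 of them by at least 2-fold, and 1646 of the 1647 moved the same way in the 3 pairs. The counts of higher genes were 357, 196 or 728 without replicate 1, 2 or 3 of that time, 183 with no replicate block and 1553 without 24 h replicate 3. The counts of lower genes under the same settings were 245, 165, 453, 137 and 1138 in that order.

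At 24 h, cell cycle transcripts were higher in sheared cells. CDK1, the kinase that starts mitosis, rose from 54.7 ± 26.6 to 309 ± 277 CPM, by 2.22 ± 0.17 (adjusted p = 8.52e-07, edgeR), and UBE2C, which marks mitotic proteins for destruction, from 52.8 ± 35.9 to 223 ± 171 CPM, by 2.01 ± 0.12 (adjusted p = 6.15e-08). All 37 genes of the G2/M and mitosis list rose, over all genes and adjusted over the list alone, with a median of 1.30 (camera adjusted p = 2.34e-77, and adjusted p = 0.108 with an estimated correlation). Of 32 G1/S and DNA replication genes 21 rose, with a median of 0.86 (24 adjusted over the list alone; camera adjusted p = 3.40e-18, and adjusted p = 0.319 with an estimated correlation). Without 24 h replicate 2, 13 G1/S genes rose and 1 fell. CDT1, which licenses replication origins, rose by 1.91 ± 0.19, and TYMS, which makes thymidylate, by 1.38 ± 0.16. RRM2, a subunit of ribonucleotide reductase, rose by 2.26 ± 0.20 and KRT4, an epithelial keratin, by 2.95 ± 0.24, from 2.22 ± 1.27 to 17.9 ± 12.3 CPM (adjusted p = 1.40e-06). The sheared replicate 3 library stood apart at this time, with 28.2% of counts in its 100 most abundant genes, and 36 of the 37 G2/M and mitosis genes rose without its pair.

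Interferon-stimulated genes were lower in sheared cells at 24 h as well. Of 35 tested, none rose and 31 fell, with a median of -1.20 (32 adjusted over the list alone; camera adjusted p = 1.96e-50, and adjusted p = 0.0916 with an estimated correlation). MX2, a GTPase that blocks viruses, fell from 12.2 ± 5.57 to 1.92 ± 1.17 CPM (-2.72 ± 0.23, adjusted p = 1.33e-06), and OAS2 from 105 ± 30.7 to 26.2 ± 5.45 CPM (-1.97 ± 0.15, adjusted p = 4.94e-07). IFIT1, which binds foreign RNA, fell from 73.1 ± 32.5 to 20.7 ± 7.13 CPM (-1.77 ± 0.13).

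Transcripts of lipid synthesis were also lower at 24 h. Of 25 genes of cholesterol synthesis and uptake none rose and 18 fell, with a median of -0.60 (20 adjusted over the list alone; camera adjusted p = 4.71e-16, and adjusted p = 0.239 with an estimated correlation). LSS, which forms the first sterol ring, fell from 263 ± 80.0 to 121 ± 50.8 CPM (-1.17 ± 0.11), and DHCR7, which makes cholesterol in the last step, from 530 ± 90.3 to 288 ± 31.3 CPM (-0.87 ± 0.12). Of 17 genes of fatty acid synthesis none rose and 11 fell, with a median of -0.77 (13 adjusted over the list alone; camera adjusted p = 1.30e-12, and adjusted p = 0.155 with an estimated correlation), FADS2 by -1.21 ± 0.12. HMGCS1 passed (-0.68, adjusted p = 0.0206), with an adjusted p of 0.0783 without 24 h replicate 1 and 0.127 without 24 h replicate 2. HOXB13, a prostate homeobox gene in the list of androgen-dependent prostate cells, fell from 289 ± 17.7 to 144 ± 71.1 CPM (-1.13 ± 0.21). That list had 3 of 8 members that fell, with a median of -0.45 (4 adjusted over the list alone; camera adjusted p = 0.0142, and adjusted p = 0.280 with an estimated correlation). The other 2 falls lost their calls without 24 h replicate 1, 2 or 3, with an adjusted p of 0.0668, 0.118 or 0.0821 for SLC45A3 and of 0.169, 0.0537 or 0.127 for FOLH1. The falls in that list numbered 1, 3 or 1 without these pairs, and 1 without any 1 of the 3 h pairs.

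Some genes of glycolysis, the TCA cycle and the respiratory chain rose at 24 h. For these lists too, none matched on abundance and length were drawn, and a trend shared with other genes stays open. Of 24 glycolysis genes 6 rose and none fell, with a median of 0.31 (7 adjusted over the list alone; camera adjusted p = 0.0169, and adjusted p = 0.833 with an estimated correlation). LDHB, a lactate dehydrogenase subunit, rose from 236 ± 21.6 to 379 ± 109 CPM (0.65 ± 0.14, adjusted p = 0.00336). LDHA changed by 0.37 ± 0.12 (adjusted p = 0.0435), and its adjusted p was 0.0962 without 24 h replicate 1 and 0.284 without 24 h replicate 3. The glucose transporter gene SLC2A1 (0.42, adjusted p = 0.157) and the hexokinase gene HK2 (0.58, adjusted p = 0.176) did not pass. Of 25 TCA cycle genes 5 rose and 1 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.0418, and adjusted p = 0.833 with an estimated correlation); the fall was that of IDH1 (-0.64 ± 0.11), which makes cytosolic NADPH. In the nuclear-encoded respiratory chain 22 of 49 rose, with a median of 0.33 (35 adjusted over the list alone; camera adjusted p = 5.67e-09, and adjusted p = 0.452 with an estimated correlation). Without the pair of the sheared replicate 3 library the camera adjusted p was 0.376 for glycolysis and 0.623 for the TCA cycle. Without 24 h replicate 1, 2 or 3, the rises numbered 4, 8 or 1 in glycolysis, 7, 5 or 2 in the TCA cycle, where 2 fell without replicate 3, and 13, 16 or 11 in the respiratory chain. Without 3 h replicate 2 they numbered 3 in glycolysis and 14 in the respiratory chain, and 1 glycolysis gene fell without 12 h replicate 2.

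Ribosomal protein genes and some cytoskeletal genes rose at 24 h as well. Of 48 cytosolic ribosomal proteins 46 rose, with a median of 0.53 (48 adjusted over the list alone; camera adjusted p = 3.62e-24, and adjusted p = 0.452 with an estimated correlation). They made up 5.58% ± 0.0618 of counts in static and 7.15% ± 0.526 in sheared libraries, and the 100 most abundant genes 21.3% ± 1.23 and 25.4% ± 2.96. Of 23 YAP/TAZ target genes 9 rose and 2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.00118, and adjusted p = 0.619 with an estimated correlation), with AXL, a receptor tyrosine kinase, at 0.82 ± 0.12. CCN1 (1.27, adjusted p = 0.0400) had an adjusted p of 0.0871 without 24 h replicate 1 and 0.173 without 24 h replicate 3, and CCN2 did not pass (0.04, adjusted p = 0.964). SRF and actin cytoskeleton genes had 7 of 25 that rose and 1 that fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.00463, and adjusted p = 0.833 with an estimated correlation). The hypoxia list had 4 of 25 that rose (4 adjusted over the list alone; camera adjusted p = 0.00971, and adjusted p = 0.833 with an estimated correlation). Membrane repair and ESCRT genes had 5 of 29 that rose, CAV1 by 1.29 ± 0.10 (6 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0360, and adjusted p = 0.282 with an estimated correlation). Without the pair of the sheared replicate 3 library the camera adjusted p was 0.379 for the SRF list, 0.165 for the hypoxia list and 0.0737 for the membrane repair list. Without 24 h replicate 1, 2 or 3, the rises numbered 28, 45 or 42 among ribosomal proteins, 4, 11 or 4 among YAP/TAZ targets, 6, 9 or 3 in the SRF list and 2, 6 or 0 in the hypoxia list. In the hypoxia list they numbered 2 without 12 h replicate 1 or any 1 of the 3 h pairs, and in membrane repair 1 gene fell without 24 h replicate 1 or 12 h replicate 2.

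Over all genes 1387 were higher and 1225 lower in sheared cells at 24 h, 339 and 225 of them by at least 2-fold, and 2528 of the 2612 moved the same way in the 3 pairs. With no replicate block 593 were higher and 320 lower, and in a fit of the 6 libraries of the time alone 481 and 280. Without 24 h replicate 3, 609 were lower.

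**Figure D2:**
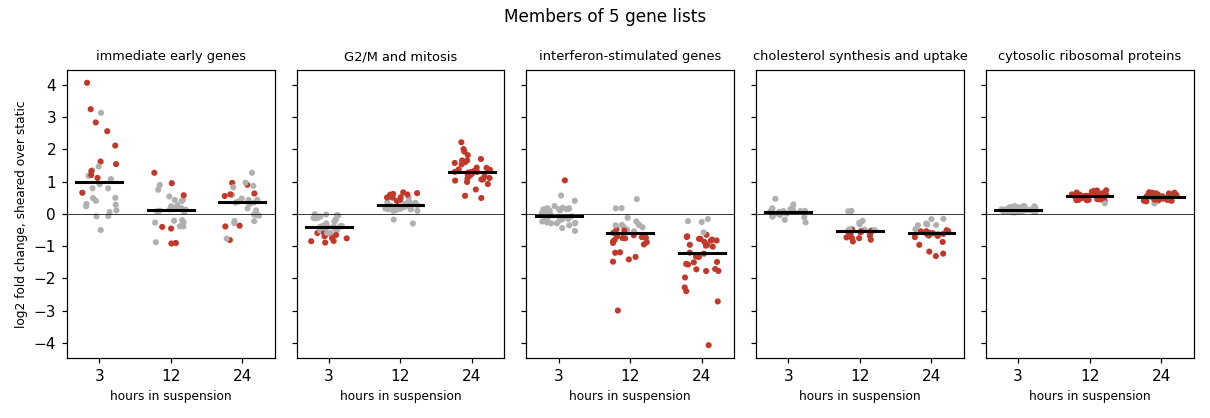
Log2 fold change (sheared against static) of each tested member of 5 lists at 3 h, 12 h and 24 h; red points are members with an adjusted p below 0.05 (edgeR) and black bars are medians. The median of the immediate early genes was 1.00 at 3 h, and those of the G2/M and mitosis genes were -0.40, 0.27 and 1.30 at the 3 times.

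Lists that did not pass camera at any time are given by their lowest and highest adjusted p over the 3 times. These were the pentose phosphate pathway and NADPH (0.621 to 0.649), fatty acid oxidation and PPAR targets (0.541 to 0.922), the integrated stress response (0.0981 to 0.922), the heat shock response (0.0966 to 0.658), and metallothioneins (0.326 to 0.637). The others were p53 targets (0.0981 to 0.284), replication-dependent histones (0.0882 to 0.765), mesenchymal genes (0.0836 to 0.310), invasion genes (0.0966 to 0.762), apoptosis and anoikis (0.312 to 0.957), and autophagy and lysosome (0.0966 to 0.637). Members still passed one by one: BAG3, a chaperone cofactor, fell at 3 h (-0.72, adjusted p = 0.00144, and 0.0695 without 3 h replicate 2), 12 h and 24 h (-1.08 and -0.68), and TRIB3, a pseudokinase induced by ATF4, fell at 12 h (-1.15 ± 0.17) while CTH, which makes cysteine, rose (1.13 ± 0.14). The epithelial cadherin gene CDH1 fell at 12 h (-0.51, adjusted p = 0.00709, and 0.0643 without 12 h replicate 2) and at 24 h (-0.49, adjusted p = 0.00577), whereas VIM, an intermediate filament of mesenchymal cells, did not pass at any time (0.12, -0.07 and 0.32). The median and the mean of a list differed in sign for the integrated stress response at 3 h and 24 h, the unfolded protein response, the invasion list and the androgen-dependent list at 3 h. They also did so for fatty acid oxidation, heat shock, NF-kB and fibroblast and endothelial lists at 12 h, and for apoptosis and anoikis at 12 h and 24 h. The test took the sign of the median for the invasion list at 3 h and for the heat shock, NF-kB, apoptosis and fibroblast and endothelial lists at 12 h, and that of the mean for the others. For haematopoietic cells at 24 h the test was positive with the median and the mean negative. Of the 102 list and time tests, 37 passed with camera's preset correlation and 0 with an estimated correlation, where 15 had an unadjusted p below 0.05. By fry, which asks only whether the members move on balance one way and does not compare them with other genes, 21 passed.

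The shear effect itself differed between times. NR4A3 had 4.07 at 3 h and 0.06 at 12 h, a difference of -4.01 ± 0.49 (adjusted p = 5.19e-04), and the circadian gene PER2 changed from 1.37 to -1.30, a difference of -2.66 ± 0.26 (adjusted p = 1.48e-04). Between 3 h and 24 h the difference was -3.22 ± 0.34 for IL11, -2.87 ± 0.30 for MX2, and 2.45 ± 0.18 for CDCA8, a subunit of the chromosomal passenger complex that went from -0.82 to 1.63. Between 12 h and 24 h, TRIM29 went from 1.19 to 0.00, and the mucin gene MUC2 from 1.20 to -0.71 (-1.91 ± 0.21, adjusted p = 7.13e-04), although MUC2 did not pass without the replicate block (adjusted p = 0.659). Of the G2/M and mitosis genes, 9 had a larger shear effect at 12 h than at 3 h, 36 at 24 h than at 3 h, and 23 at 24 h than at 12 h. Of the immediate early genes, 7 had a smaller effect at 12 h than at 3 h, and of the interferon-stimulated genes 26 had a lower one at 24 h than at 3 h. The 9 became 3, 3 or 4 without 3 h replicate 1, 2 or 3 and 3, 3 or 4 without 12 h replicate 1, 2 or 3, and 19 or 29 without 24 h replicate 2 or 3. The 23 became 15 without 3 h replicate 2 and 11, 3 or 5 without 12 h replicate 1, 2 or 3, and the 7 became 11 or 13 without 24 h replicate 2 or 3. With no replicate block the 9, 36 and 23 became 0, 28 and 0, the 7 became 6 and the 26 became 11. In total, 214 genes differed between 3 h and 12 h, 895 between 3 h and 24 h, and 101 between 12 h and 24 h, and the batch date also differed in both comparisons with 3 h. Without the replicate block these counts were 29, 258 and 1. The count between 12 h and 24 h was 45, 17 or 19 without 12 h replicate 1, 2 or 3. It was 185 without 24 h replicate 1. That between 3 h and 12 h was 74, 59 or 80 without 3 h replicate 1, 2 or 3, and 90 or 72 without 12 h replicate 1 or 2. That between 3 h and 24 h was 469, 431 or 457 without 3 h replicate 1, 2 or 3.

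Calls overlapped between times. Of the genes higher in sheared cells, 528 were shared by 12 h and 24 h, where independence would give 87.3, and 46 by 3 h and 12 h, where it would give 10.7 (Fisher's exact p = 9.41e-18, two-sided). Of the genes lower in sheared cells, 407 were shared by 12 h and 24 h (55.7 under independence, Fisher's exact p = 6.51e-282, two-sided). Fisher's test takes genes as independent units, which they are not, and all times share 1 model and its dispersion estimates. Its p-values therefore do not measure the spread between pools. Across genes, which are not independent replicates, Pearson's correlation of the shear effects was 0.20 between 3 h and 12 h, 0.11 between 3 h and 24 h, and 0.57 between 12 h and 24 h. The shear effect averaged over the 3 times passed for 3903 genes, 2167 higher and 1736 lower, and for 1772 with no replicate block.

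**Figure D3:**
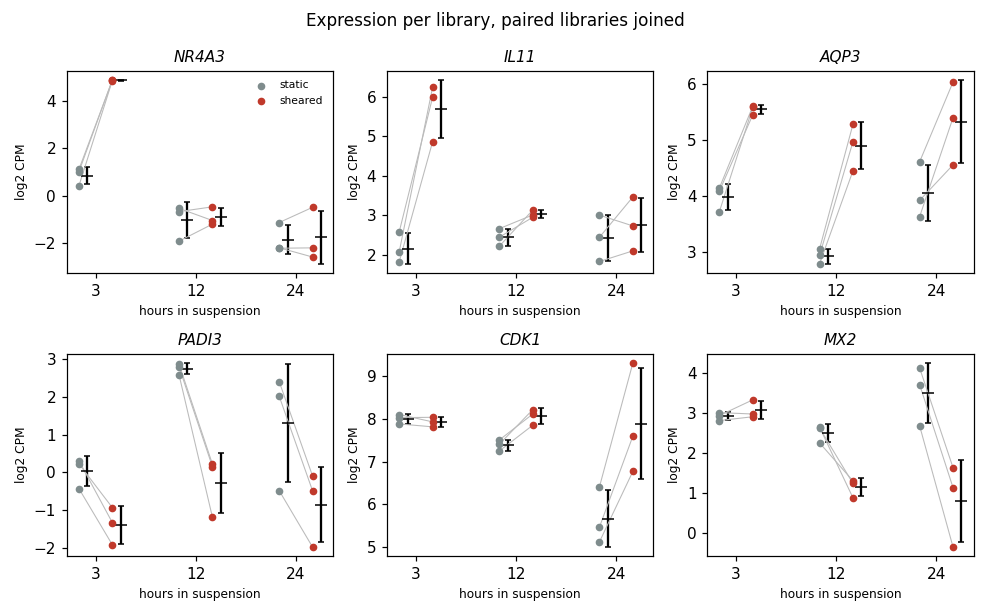
Abundance (log2 CPM) of NR4A3, IL11, AQP3, PADI3, CDK1 and MX2 in each of the 18 libraries, static and sheared, at 3 h, 12 h and 24 h; lines join the libraries of 1 pool and bars are mean ± SD. NR4A3 separated the groups at 3 h and MX2 at 24 h.

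Static cells changed between 12 h and 24 h in suspension, the background of the shear effects at those times. MUC2, a secreted mucin, rose from 3.73 ± 0.341 to 52.8 ± 21.4 CPM, by 3.81 ± 0.30 (adjusted p = 1.49e-06, edgeR), and KRT20, a keratin of differentiated epithelium, from 2.28 ± 0.0745 to 14.9 ± 2.15 CPM, by 2.69 ± 0.21. HELLS, a chromatin remodeller of dividing cells, fell from 6.01 ± 0.675 to 1.08 ± 0.25 CPM (-2.49 ± 0.23), and BRCA1, a DNA repair gene, from 14.2 ± 1.08 to 2.82 ± 0.907 CPM (-2.33 ± 0.21). KRT4, which was higher in sheared cells at 24 h, fell from 14.7 ± 2.22 to 2.22 ± 1.27 CPM (-2.73 ± 0.27) in static cells.

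In the static cells 27 of 35 interferon-stimulated genes rose and none fell (29 adjusted over the list alone), OAS1 by 2.16 ± 0.19. Of 25 genes of cholesterol synthesis and uptake 20 rose and none fell (23 adjusted over the list alone), FDPS, which makes farnesyl diphosphate, by 1.33 ± 0.13. Fatty acid synthesis had 8 of 17 that rose, the unfolded protein response 14 of 22, with the chaperone gene HSPA5 at 0.94 ± 0.13, and the integrated stress response 18 of 39, with the glutamine transporter gene SLC1A5 at 1.49 ± 0.12. Epithelial genes had 15 of 29 that rose and 3 that fell, among the rises KRT8 (1.12 ± 0.17). Of 37 G2/M and mitosis genes 33 fell and none rose (35 adjusted over the list alone), ANLN, which acts in cytokinesis, by -2.06 ± 0.17. Of 32 G1/S and DNA replication genes 24 fell and 1 rose (27 and 1 adjusted over the list alone), TYMS by -1.65 ± 0.15. Replication-dependent histones had 8 of 13 that rose, and cytosolic ribosomal proteins 13 of 48. MALAT1 fell from 37.6 ± 1.94 to 16.4 ± 7.35 CPM (-1.21 ± 0.22). The rises among ribosomal proteins numbered 3, 2 or 21 without static 12 h replicate 1, 2 or 3 and 7 without static 24 h replicate 3, and 0 epithelial genes fell without static 12 h replicate 1 or 2 or static 24 h replicate 2. In fatty acid synthesis 1, 2 or 1 fell without static 12 h replicate 3, static 24 h replicate 1 or static 24 h replicate 2, and 2 genes of the unfolded protein response fell without static 24 h replicate 1.

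Between 12 h and 24 h, 2499 genes were higher and 2306 lower in static cells, 464 and 632 of them by at least 2-fold. The libraries also differed in their trend with GC content. Spearman's correlation of GC content with deviations from each gene's mean log2 CPM was -0.394, -0.441 and 0.142 in static 12 h replicates 1, 2 and 3. It was 0.110, 0.474 and 0.316 in those of 24 h. These static counts were not repeated with GC and length offsets, so GC content stays open as a source of part of them. Without static 12 h replicate 1, 1451 were higher and 1443 lower, and without static 12 h replicate 2, 1456 and 1398.

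Lists of other cell types and of nuclear RNA were followed in each library. The summed CPM of a library ranged from 267 to 667 for genes of androgen-dependent prostate cells, of which HOXB13 was the most abundant, from 15.5 to 106 for haematopoietic cells, led by CD68, and from 33.1 to 134 for fibroblast and endothelial cells, led by PECAM1. Haematopoietic genes did not pass camera at any time (adjusted p 0.637 to 0.922). Fibroblast and endothelial genes had 2 of 7 that fell at 12 h, with a median of -0.45 and a mean of 0.03 (camera adjusted p = 0.0360, and adjusted p = 0.751 with an estimated correlation); 1, 0 or 1 fell without 12 h replicate 1, 2 or 3. Nuclear-retained RNAs, a sign of how cleanly the cytosol was separated, summed to between 145 and 418 CPM and did not pass (adjusted p 0.226 to 0.762), but at 3 h the adjusted p was 0.0394 without the 24 h replicate 3 pair. MALAT1 was at 41.2 ± 2.12 CPM in static and 33.0 ± 4.69 CPM in sheared libraries at 12 h, and 15.9 ± 7.78 and 27.6 ± 21.2 at 24 h.

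The authors' deposited DESeq2 tables gave 118 genes higher and 23 lower at 3 h, 448 and 350 at 12 h, and 862 and 483 at 24 h, at an adjusted p below 0.05. Of these, 132 at 3 h, 794 at 12 h and 1332 at 24 h were called here in the same direction and 0 in the opposite one. Across genes, Pearson's correlation of the log2 fold changes was 0.995, 0.996 and 0.995 at the 3 times.

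On the GRCh38 genome, 6 of the named protein-coding genes lie as follows, with positions counted from 1. NR4A3 (Gene ID 8013) lies on chromosome 9 from 99821855 to 99866891, AQP3 (Gene ID 360) on chromosome 9 from 33441154 to 33447633, and IL11 (Gene ID 3589) on chromosome 19 from 55364389 to 55370463. PADI3 (Gene ID 51702) lies on chromosome 1 from 17249098 to 17284233 and MX2 (Gene ID 4600) on chromosome 21 from 41361943 to 41409390. KRT4 (Gene ID 3851) lies on chromosome 12 from 52806549 to 52814551. Some named genes share exon bases with a neighbour, so reads there can be counted for either: RRM2 shares 27.9% with another gene on its strand and LINC00261 97.3%. On the opposite strand, VIM shares 34.3%, MNS1 22.9%, HMGCS1 19.9% and ARHGAP24 17.0%. Keratins, ribosomal proteins and FAM72A have close paralogs or pseudogenes that reads can match.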

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

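Of the tests reported in this part, those that leave out a pair or the replicate block for the G2/M genes and the comparisons of batch dates were chosen only after the result was seen.

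What drew attention to these results is that the shear effect, the log2 fold change of sheared over static cells, differed between times by an edgeR test of the difference itself. Such a difference was found for 214 genes between 3 h and 12 h, 895 between 3 h and 24 h and 101 between 12 h and 24 h. In 10 splits of the 6 pairs each, the highest count of the other splits was 0, 0 and 3, and only the real split (1 of 10) gave as many; 10 splits are too few for a share under 0.05. Of the 83 named genes checked, 51 differed, with adjusted p from 1.66e-06 to 0.0438. These genes had been named for large effects at 1 time, for small p-values of these same differences, or by a fixed list. How they were chosen tends to raise that share, so it does not stand for all genes. Over all 15189 tested genes 1.41%, 5.89% and 0.665% differed, in the order above.

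From 3 h to 24 h the shear effect was lower for genes that had risen at 3 h: IL11 by a difference of -3.22, NR4A2 -3.14, RRAD -2.81, RASD1 -2.79, ADAMTS1 -1.88, ATF3 -1.81, GEM -1.68, CD55 -1.59, JUND -1.51 and KLF4 -1.20. It was also lower for members of the interferon-stimulated list, MX2 -2.87, BST2 -2.69, CMPK2 -2.39 and OAS2 -1.87, and for HMGCS1 of the cholesterol list -1.15. Others with a lower effect at 24 h were SLC7A8 -2.95, COL2A1 -2.45, FCGR2A -2.23, ITGB2-AS1 -2.14, KRT20 -1.88 and TRIM29 -1.10.

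From 3 h to 24 h the shear effect was higher for members of the G2/M list, CDK1 by a difference of 2.30, KIF14 2.17, UBE2C 2.06 and CENPA 1.89, and for RRM2 of the G1/S list, 2.22. Further genes with a higher effect were CDCA8 2.45, FAM72A 2.38, HELLS 2.23, ASPM 2.18, CCNF 1.91, SKA1 1.87, DTL 2.47, KRT4 2.64, MARCHF4 2.61, MND1 2.53, MNS1 1.91, CYP1A1 1.84 and PTX3 1.13.

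From 3 h to 12 h the difference was -4.01 for NR4A3, -2.66 for PER2, -2.56 for TSPEAR, -1.73 for TCN1, -1.59 for PADI2 and -1.01 for SLC7A11, and it was 1.11 for ST6GAL2, 1.48 for BMF, 1.61 for OXTR and 2.14 for RPSAP52. From 12 h to 24 h it was -1.91 for MUC2 and -1.27 for OSBP2.

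G2/M and mitosis genes were lower in sheared cells at 3 h (10 of 37 fell, adjusted p = 0.310 with an estimated correlation and 0.0846 by fry, and 2 without any 1 of the 3 h pairs or 0 with no replicate block, where the median stayed at -0.43 to -0.40) and higher at 24 h (37 of 37 rose, adjusted p = 0.108 with an estimated correlation). The tables argue against the sheared 24 h replicate 3 library as the whole cause of the 24 h part, since 36 of the 37 rose without its pair. They also argue against the batch date for the part between 12 h and 24 h, which share 1 batch date and where 23 members differed: the median difference was 0.78 to 1.19 with any 1 pair left out, although only 3 members differed without 12 h replicate 2 and 0 with no replicate block. Between 3 h and 24 h, where 36 members differed, the time and the batch date cannot be told apart, because the 3 h libraries have another batch date than those of 24 h. In static cells 33 of the 37 fell from 12 h to 24 h, so the 24 h part is relative to that decline, and no biological explanation was tested.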

How the results depend on the processing

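The alternatives with GC and length offsets, with the non-legacy quasi-likelihood test, and without the 24 h replicate 3 pair for other times and for lists were chosen only after the result was seen. Of 472 results for named genes, 466 kept their direction under every alternative run for them; 447 were past the threshold and 250 stayed past it under every alternative. With no replicate block in place of the pairs, 153 of 333 lost their call.

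Counts that moved by over 1.5 times were these, and the cause was not tested unless given. With no replicate block, 58 genes were higher and 6 lower at 3 h, 183 and 137 at 12 h, 593 and 320 at 24 h, and 1772 on the mean of the times. Differences between times were then 29 (3 h and 12 h), 258 (3 h and 24 h) and 1 (12 h and 24 h). With no filter on low counts, 331 were higher and 119 lower at 3 h, with 588, 1513 and 323 differences. With the DESeq2 Wald test 79 were lower at 3 h, with 402 differences between 3 h and 12 h and 190 between 12 h and 24 h. With only the 6 libraries of the time, 816 were higher and 650 lower at 3 h, and 481 and 280 at 24 h. The order of 3 h and 24 h was then the reverse of that in the main fit, so the counts do not rank these times. Of the list and time tests, 0 passed with an estimated correlation (15 at an unadjusted p below 0.05) and 21 by fry.

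Leaving out 1 pair or static library gave 70 to 304 genes higher and 9 to 142 lower at 3 h, 196 to 1553 and 165 to 1138 at 12 h, and 609 to 1396 lower at 24 h. Differences were 59 to 154, 431 to 1209 and 17 to 185 in the order above. Static cells had 1451 to 2915 genes higher and 1398 to 2880 lower at 24 h. Lists lost their camera call without the 24 h replicate 3 pair (SRF, glycolysis, TCA cycle, hypoxia and membrane repair at 24 h), with no replicate block (hypoxia at 3 h, membrane repair at 12 h and 24 h, TCA cycle at 24 h) and with GC and length offsets (TCA cycle and membrane repair at 24 h). Other lists gained a call: 5 without that pair (MYC targets, autophagy and lysosome, and the unfolded protein response at 24 h, the integrated stress response at 12 h and nuclear-retained RNAs at 3 h), 1 with no replicate block and 2 with the offsets. Reversals were seen only for genes not past the threshold, and the cause was not tested. At 12 h VIM was 0.054 with no replicate block and -0.39 to 0.20 with 1 pair left out, and SLC2A1 -0.042 with GC and length offsets and -0.12 to 0.22 with 1 pair left out. At 24 h, with 1 pair left out, ATF3 was -0.22 to 0.68, FOS -0.26 to 0.94, CCN2 -0.28 to 0.31 and VIM -0.069 to 0.80. Depth limits what can be called among genes with few counts.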

Other observations

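Of the tests reported in this part, the recounts of genes that passed at all 3 times, those with GC and length offsets or without the 24 h replicate 3 pair for the ribosomal proteins, and the 3 tests of single lists with no library in common, were chosen only after the result was seen.

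A set of genes passed at all 3 times, 28 higher and 13 lower in sheared cells; AREG, DKK1 and CDKN2B are named here after their values were seen. The counts depended on the processing: they were 10 to 39 and 0 to 21 with 1 pair left out, 2 and 0 with no replicate block, 64 and 25 with no filter on low counts, and 53 and 38 with only the 6 libraries of each time. AQP3, with log2 fold changes of 1.56, 1.99 and 1.28 at 3 h, 12 h and 24 h, was the only gene that passed at all 3 times under each of the 19 alternatives. AREG, a ligand of the EGF receptor, had 0.87, 1.16 and 0.96 and TGFB2 had 1.05, 0.91 and 0.87, and both were lost only with no replicate block. DKK1, an inhibitor of Wnt signalling, had 1.31, 1.42 and 0.95 and was lost at a time without 3 h replicate 3 or 24 h replicate 3. Among the lower genes, the CDK inhibitor gene CDKN2B had -0.72, -0.92 and -0.84 and was lost without 3 h replicate 2 and with no replicate block. PADI3 had -1.68, -3.08 and -2.57 but passed at all 3 times under only 10 of the 19.

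The hypothesis is that sheared 24 h cells may be less far along the change that static cells undergo between 12 h and 24 h; over 14804 genes the covariance of these changes was -0.109 (Pearson's r = -0.379 across genes, which are not independent replicates). Both changes hold the static 24 h libraries. In 200 simulations with no change these alone gave a mean covariance of -0.0270 and a mean r of -0.495, so the r is no evidence of a change. The simulations drew all libraries from 1 mean per gene, without pool differences and with the same dispersion at all times. They may therefore misstate what the shared libraries give. With no library in common the covariance was -0.134, -0.141 and -0.0111 when static 24 h replicate 1, 2 or 3 stood in the static change. The shared libraries thus stay open as a source over all genes. For 3 lists they are argued against: with no library in common the shear effect stayed opposite to the static change in all 3 arrangements, with its median nearest to 0 at 1.08 for G2/M and mitosis, -0.988 for interferon-stimulated genes and -0.446 for cholesterol synthesis and uptake. The cholesterol list, however, had a median shear effect of -0.54 at 12 h and -0.60 at 24 h, and 0 of its 25 members differed between these times. That effect was present at 12 h, so it cannot be read as a slower change from 12 h to 24 h. The interferon list also had a median of -0.60 at 12 h, and 2 of its 35 members had a lower effect at 24 h. With GC and length offsets the covariance was -0.109, which argues against transcript length and GC content as the whole cause. The sheared 24 h replicate 3 library stays open. Without its pair in the shear effect the covariance was -0.0722, with static 24 h replicates 1 and 2 still in both changes. The -0.0111 also left that pair out of the shear effect, with no library in common. There static 24 h replicate 3 alone stood for 24 h in the static change. The -0.0111 therefore cannot tell the sheared library from that static one. Other lists moved the same way in both changes, against the hypothesis for them: the medians of the static change and the shear effect were 0.27 and 0.53 for ribosomal proteins, 0.23 and 0.33 for the respiratory chain, and 0.19 and 0.19 for the SRF list. Random lists matched to the ribosomal proteins on abundance and length had a median shear effect of 0.263 at 24 h. None were drawn for the respiratory chain or the SRF list. A trend shared with other genes therefore stays open as a source of part of these effects.

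Ribosomal protein transcripts were higher in sheared cells at 12 h and 24 h, with medians of 0.56 and 0.53 over 48 genes (adjusted p = 0.319 and 0.452 with an estimated correlation). With GC and length offsets the medians were 0.53 and 0.48, and without the 24 h replicate 3 pair the median at 24 h was 0.535, which argues against length and GC content and against that library as the whole cause. In 10000 random lists matched on abundance and length from 50 neighbours each, the highest median was 0.504 at 12 h and 0.502 at 24 h. The median of these lists was itself 0.264 and 0.263. Genes of like abundance and length thus rose too, but less than the ribosomal proteins. The draws took genes independently, whereas the estimated correlation within the ribosomal list was 0.733 and 0.732. They therefore cannot say how often a list of correlated genes would reach its medians. The neighbours were also less abundant, with a median log2 CPM of 9.59 against 9.87. A shared trend with abundance and length stays open as a source of part of the rise. A difference in how much of the cytosolic RNA was released by the lysis, and a change of these transcripts within the cells, stay open and were not tested.

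Other splits of the libraries were run for each count. Of the 10 splits of the 6 libraries of a time, 1 gave as many genes as the real one (itself): 222 at 3 h against 0 in the highest other split, 1647 at 12 h against 21, and 2612 at 24 h against 1658. The 24 h splits with 1658 genes parted only the replicate 3 pair and so rest on the difference within that pair, and the other splits that part all 3 pairs gave 0. For static cells the real split gave 4805 and the highest other 0. With 10 splits a share under 0.05 cannot be reached. For the shear effect averaged over the 3 times, 1 of 60 swaps within pairs gave as many genes as the real 3903, the real one, and the highest other gave 2455, so chance is excluded at 0.05.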
